A study of Mus musculus with 4 samples.

How the data were processed

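Single-cell RNA sequencing of mouse ETX embryoids was analysed from 4 libraries, 1 each for day 4, day 5 early, day 5 mid and day 6. Per the labels, 10 structures were pooled per stage, dissociated with TrypLE for 5 minutes at 37 °C, passed through a 40 µm strainer and loaded at 15000 cells per library on a droplet platform that captures 3′ ends, and at least 25000 raw reads per cell were aimed for. The deposited matrices hold raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger 6.0.0 (per the file headers) against the mm10 genome (submitters' processing notes), and the annotation release was not given in the sources used here. They list 32288 features, of which 32285 are genes and 3 are reporter sequences (DSRED, GFP and EGFP), and GFP had no counts in any lineage. Every deposited barcode held at least 500 UMIs, and how the authors chose barcodes was not stated. The library called day 5 mid in its title is called late in the name of its deposit, and the title was followed.

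Barcodes with under 2000 UMIs were set aside (1325, 1710, 1519 and 5075 in the order of the stages), then those with over 10% mitochondrial UMIs (83, 233, 97 and 506). Doublets were scored with the Scrublet method of scanpy 1.11.5 in each library (30 components, expected rate 6%), and the cells with the highest scores were removed up to a rate of 0.8% per 1000 cells, which took 344, 124, 536 and 2036 cells. The remaining 6214, 3819, 7653 and 13916 cells (31602 in all) had a median of 4294, 5262, 3878 and 3145 genes. The expected doublet rate by this rule was 12.8% at day 6, where the deposited barcodes (21533) exceeded the cells loaded.

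All libraries were clustered together without batch correction, since each stage is 1 library and a correction would remove the stages too. Counts were scaled per cell and log-transformed, 2000 variable genes were scaled to at most 10 standard deviations, and 30 principal components, 15 neighbours and the Leiden method at resolution 1 (5 iterations, seed 1) gave 24 clusters. Clusters were named from marker lists of 25 classes, each in 1 of 3 lineages: a marker counted at 10 CPM or more and at least 2-fold above the other clusters together (pseudocount 5), at least 3 markers of a class were needed, the class with the highest mean log2 ratio gave the name, and a cluster stayed unnamed where its 10 leading genes held at least 2 more markers of another lineage than of its own. Clusters with a high UMI count (1.5-fold) and doublet score (2-fold), or with a low UMI count and no marker among their leading genes, were left unnamed. In all 19 clusters were named and 5 were not, holding 15.5%, 21.1%, 11.6% and 4.38% of the cells of the 4 stages. A check that the leading genes hold no more markers of another class than of the named class failed for epiblast-like clusters 3, 7 and 9, the primitive erythroid-like cluster, the ectoplacental cone-like cluster and nascent mesoderm-like cluster 16, so clusters are referred to by number, stages are compared within lineages, and where the closing section compares classes it names their clusters.

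Counts were summed per library and lineage and given as CPM with exact Poisson intervals. Ratios of libraries have exact conditional binomial intervals, and shares of cells have Clopper-Pearson intervals, all at 95% and for counting error only. A gene with no counts in a library was compared with a floor of 3 counts there. Consecutive stages were compared within each lineage with at least 100 cells, and no test was made, as 1 library per stage gives no spread between replicates. Named genes were, for each comparison and lineage, the 4 with the largest and the 4 with the smallest ratio among genes at 50 CPM or more in the higher library and with a level there of at least 0.2 of their highest level in any lineage of it. Mitochondrial and ribosomal protein genes, predicted gene models, Xist, Tsix and Y-linked genes were left out of that choice. This gave 24 genes per comparison and 72 in all, with members of the gene lists, the markers and the reporters named besides.

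For each of 41 gene lists the median over members of the log2 ratio with a pseudocount of 1 CPM was taken, all members included, and members at 5 CPM or more in either library were called measured and counted as higher or lower. Intervals of medians are the central 95% over 1000 redrawn Poisson counts. Percentiles are positions among 10000 random lists of the same size drawn from the 200 genes nearest in mean expression, and describe these libraries alone. All 41 lists were computed in 3 lineages and 3 comparisons, so that extreme percentiles were bound to occur. Lists with at most 2 measured members everywhere, which covers paraxial mesoderm, cardiac and lateral mesoderm, chorion and syncytiotrophoblast, and the HOX and macrophage lists, are not described, and 0 members were measured of the primitive erythroid, node and axial mesoderm, trophoblast giant cell and 2-cell-like lists. Gene length was that of the longest protein-coding transcript in GENCODE vM21, and whether that release matches the annotation of the counts is not known.

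The groups, comparisons, marker and gene lists, cell filters, rule for named genes and most alternatives were chosen before the data were examined. The thresholds for naming clusters, the margin between lineages (a strict rule had left trophoblast clusters unnamed), the choice of the 6 list medians treated as main results, the setting aside of the naive-like cluster, the shares among named cells, the ratios relative to the other lineages and the removal of the cell with the most counts or, for Spp1, of 3 cells were chosen after. Alternatives changed the UMI minimum (1000 and a higher one), the mitochondrial maximum (5%, 20%), doublet removal, the Leiden resolution (0.5, 2), the number of variable genes (doubled), the naming, the CPM denominator, the scaling, the weighting of cells, the pseudocount (0.1, 5) and the filter on low levels.

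The procedure was tested on simulated Poisson counts. Both simulated libraries were drawn from the embryonic profile of day 4, with the UMI totals of day 4 and day 5 early, and shifted genes were picked from 2477. Such draws hold no spread between libraries or cells, no length trend and no single cells with extreme counts, so they check the calculation alone. The other lineages and comparisons were also simulated and are not given. For 50 genes each with a true fold of 2, 0.5, 4 and 0.25, the median recovered folds were 1.99, 0.502, 4.00 and 0.250, with 47, 49, 48 and 48 true values inside the interval, as were 188 of 200 unshifted genes. All 8 named genes came from the genes shifted by 4-fold, 10 of 10 shifted lists lay above percentile 97.5, and 0 of 40 unshifted lists lay outside the central 95%. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used. No sample was left out.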

Results

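Single-cell transcriptomes were collected from mouse embryo models called ETX embryoids, in which 3 kinds of stem cell are combined so that they sort into an embryonic part, an endoderm part and a trophoblast part. Per the labels, the lines were embryonic stem cells with an actin-driven green reporter, embryonic stem cells carrying transgenes for Fgfr2 and Gata6 that direct them to primitive endoderm, and trophoblast stem cells with a green reporter. The series holds 4 libraries, 1 per stage, each from 10 pooled structures: day 4, when the structures had an epiblast and a cavity; day 5 early and day 5 mid, parted by how far gastrulation had gone by eye; and day 6, when extraembryonic membranes had formed. The deposited matrices held 7966, 5886, 9805 and 21533 barcodes in that order, where 15000 cells had been loaded per library. After filtering, 6214, 3819, 7653 and 13916 cells remained, with a median of 22562, 28934, 17215 and 11062 UMIs (unique molecular identifiers, so each counts 1 captured RNA molecule) and 153572825, 124035559, 149353403 and 168287649 UMIs in total. With 1 library per stage there are no replicates, the stage and the library cannot be told apart, and no difference was tested. Levels are in counts-per-million (CPM), taken over the UMIs of all cells of a lineage in a library, and the intervals of levels, ratios and shares are exact 95% intervals that cover counting error only.

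Embryonic cells made up the largest lineage at every stage. They were 49.9% of the kept cells at day 4 (95% interval 48.7 to 51.2), 47.9% at day 5 early (46.3 to 49.5), 61.0% at day 5 mid (59.9 to 62.1) and 66.1% at day 6 (65.3 to 66.9). Extraembryonic endoderm cells, the layer that wraps the embryo and feeds it, were 22.9%, 21.5%, 17.0% and 18.2%, and trophoblast cells, which give rise to placenta, were 11.7%, 9.48%, 10.4% and 11.3%. The cells left without a name were 15.5%, 21.1%, 11.6% and 4.38%, and among named cells alone the embryonic shares were 59.1%, 60.7%, 69.0% and 69.1%. So the gap between day 5 mid and day 6 in the share of all kept cells was not seen among named cells, and the shares also depend on how well each lineage survived dissociation, which was not measured. Unnamed cluster 6, low in UMIs, had 9 of 12 visceral endoderm markers raised and held 434, 256, 264 and 384 cells, so the endoderm shares may be too low. Unnamed cluster 10 was nearest to epiblast (99, 280, 210 and 14 cells). Trophoblast cluster 12, also low in UMIs, was named. Shares among named cells leave clusters 6 and 10 out.

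**Figure D1:**
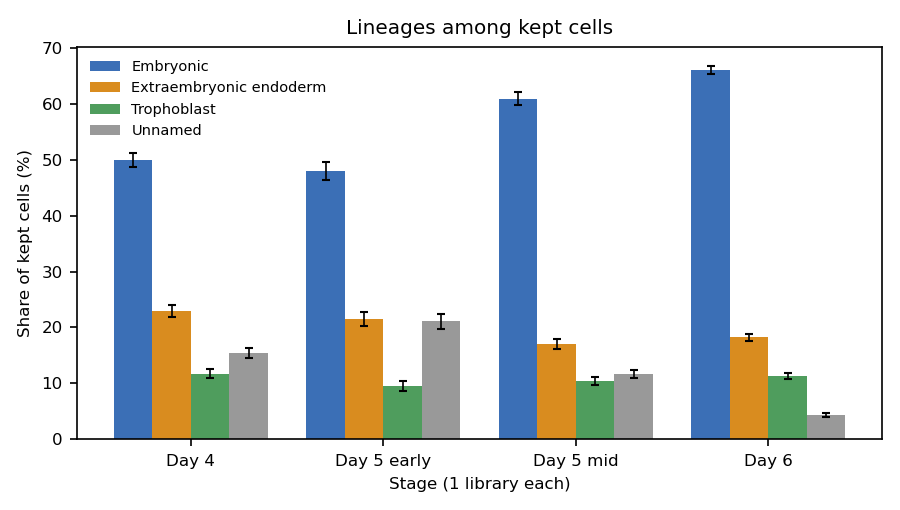
Share of kept cells (percent, y axis) in each lineage and without a name at the 4 stages (x axis, 1 library each). Bars are shares and whiskers exact 95% binomial intervals for counting error only. Embryonic cells ranged from 47.9% at day 5 early to 66.1% at day 6.

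The embryonic lineage was divided differently in every library. Epiblast-like cells fell into 4 clusters that followed the libraries: cluster 3 took 85.7% of the embryonic cells of day 4, cluster 9 took 53.9% of those of day 5 early, cluster 7 took 57.9% of those of day 5 mid and cluster 20 took 40.4% of those of day 6. Cluster 9 was led in part by Egr1 and Fosb, genes that respond to cell handling. Nascent mesoderm-like cells, the first cells to leave the primitive streak, were 32.6% of the embryonic cells of day 5 early (cluster 16) and 33.6% of those of day 5 mid (cluster 15). Cluster 23, with 5 of 8 primitive streak markers raised, took 22.6% of those of day 6. It held 0, 1 and 5 embryonic cells at day 4, day 5 early and day 5 mid. Cluster 19, with markers of extraembryonic mesoderm, the tissue of amnion, chorion and allantois, held 2773 of 9194 embryonic cells at day 6, and over the alternatives its class took from 7.85% to 19.9% of all kept cells of that stage, the highest with the settings used. Cluster 17 had 4 of 6 primordial germ cell markers raised. Dppa3, of the same markers, was there at 6.21, 11.0 and 17.5 CPM at day 5 early, day 5 mid and day 6. All embryonic cells had 18.9, 5.46 and 10.8 CPM. These primordial germ cell-like cells of cluster 17 numbered 26, 122 and 102 at day 5 early, day 5 mid and day 6, and 0 of 6214 cells at day 4. With this naming the floor of 3 cells is a share of 0.0483% at day 4, while naming each cell by its own markers gave 6.21% there. A cluster that holds mostly 1 library may mark that library and not a cell type, so these sizes were not compared between stages.

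The reporters and the sex-linked genes differed between the lineages. EGFP was at 1038, 1185, 1221 and 574 CPM in embryonic cells in the order of the stages, against 9.17, 37.8, 30.8 and 53.5 CPM in endoderm and 173, 216, 212 and 201 CPM in trophoblast, whose line also has a green reporter per the labels. The summed Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) stood at 111, 110, 81.0 and 110 CPM in embryonic cells and at 10.8 CPM or less in the other 2 named lineages. DSRED, a red reporter sequence listed with the genes, whose line the labels do not state, was highest in endoderm, with 1679 CPM at day 4, 937 at day 5 early, 364 at day 5 mid and 50.6 at day 6. Xist, the RNA that silences an X chromosome in female cells, was at 196, 191, 224 and 271 CPM in trophoblast, and at 8.71 CPM or less in the other 2 named lineages, although parietal endoderm-like cluster 1 was at 40.7 CPM at day 5 mid and the unnamed cells at 49.4, 33.8, 31.4 and 3.72 CPM. The embryonic lineage includes a naive-like cluster in which part of the cells had mostly DSRED. Gata6, named in the genotype of the endoderm line, was at 115, 129, 103 and 93.9 CPM in endoderm. Fgfr2, the other gene named there, was at 9.48, 11.4, 6.50 and 8.18 CPM in endoderm, below its 30.1, 28.6, 30.1 and 26.7 CPM in trophoblast, where it is a known receptor of stem cell signals.

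**Figure D2:**
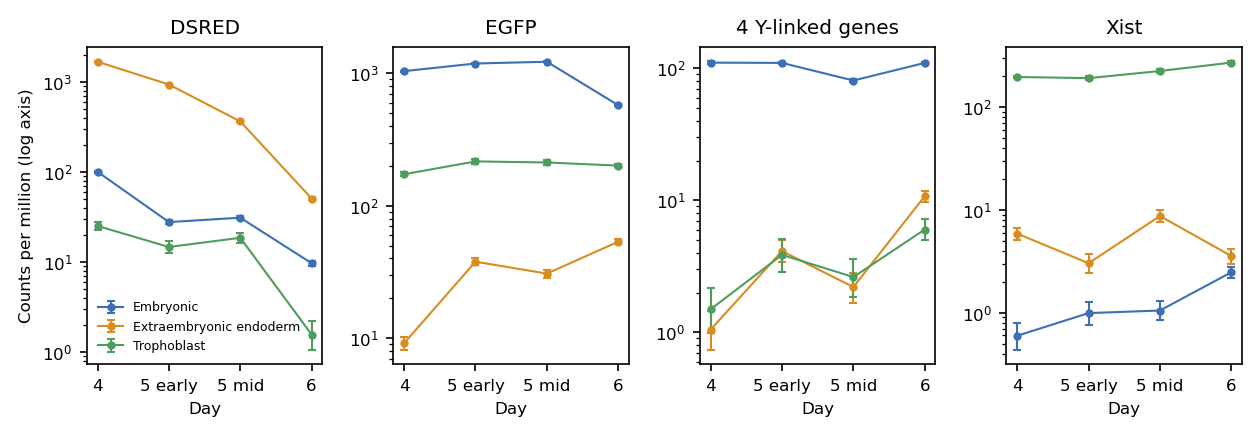
Levels of DSRED, EGFP, the summed Y-linked genes and Xist (CPM, log axis) at the 4 stages (x axis) in each lineage. Points are 1 library each and whiskers exact 95% Poisson intervals for counting error only. DSRED in endoderm was 1679 at day 4 and 50.6 at day 6.

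The first comparison, day 5 early against day 4, asks what set the structures at the start of gastrulation apart from those with an epiblast alone. In embryonic cells, genes of the primitive streak, where epiblast cells turn into mesoderm and endoderm, were far higher at day 5 early. Brachyury (T) was at 11.2 CPM at day 4 and 143 at day 5 early, Eomes at 26.7 and 186 (6.99-fold) and Mixl1 at 1.70 and 90.5 (53.3-fold, interval 44.9 to 63.9), and 8 of the 10 measured streak genes were at least 2-fold higher with none at least 2-fold lower (list median log2 ratio 2.79, percentile 100 among 10000 random lists of matched expression). Lhx1, a streak and early endoderm regulator, had the largest ratio, 0.324 against 154 CPM (476-fold, 322 to 735). Mesp1, which marks the first mesoderm, followed with 1.24 against 384 CPM (308-fold, 253 to 381), and 6 of 7 nascent mesoderm genes were at least 2-fold higher (median 2.53, percentile 100), among them Pdgfra (45.3-fold) and Snai1 (15.5-fold).

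The embryonic cells of day 5 early also had higher levels of the genes of migrating cells. All 7 mesenchymal genes were at least 2-fold higher (median log2 ratio 3.31), with Cdh2, the N-cadherin gene, at 57.3 against 4.50 CPM and the matrix gene Fn1 at 207 against 19.9 CPM, while the epithelial list had no member past 2-fold (median -0.21) and Cdh1, the E-cadherin gene, was at 72.4 against 75.1 CPM. Cyp26a1, which breaks down retinoic acid, was 92.7-fold higher (74.9 to 116). WNT targets had 4 of 5 measured members at least 2-fold higher (median 1.20), with Axin2 2.92-fold and Sp5 16.5-fold, and BMP targets 4 of 8 (median 0.96), with Msx1 13.2-fold and Msx2 9.94-fold. Naive pluripotency genes, of the state before implantation, had 3 of 10 members at least 2-fold lower and 1, Tbx3, higher (median -0.38, percentile 0). The naive-like cluster was 12.0% of embryonic cells at day 4 and 3.44% at day 5 early, and without it that median was 0.024. That cluster was named by members of the same list, so its removal cannot part fewer naive-like cells from lower levels within cells. Dppa5a stood at 1902 CPM at day 4 and 399 at day 5 early (4.77-fold lower, 4.70 to 4.83). The formative and primed epiblast list had a median of 0.06, with Pou5f1 at 977 and 1017 CPM and Utf1 at 804 and 393. The metallothionein genes Mt1 (4.79-fold) and Mt2 (4.48-fold), which bind metal ions, and Tmsb4x, an actin-binding gene, (3.22-fold) were lower at day 5 early.

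In endoderm, basement membrane genes were higher at day 5 early than at day 4. The parietal endoderm list, made of matrix genes that the whole lineage can express, had 6 of 10 members at least 2-fold higher (median log2 ratio 1.01, percentile 100), with Col4a1 at 1556 against 640 CPM and Col4a2 at 546 against 225, and Loxl2, which crosslinks collagen, was 5.66-fold higher (5.13 to 6.24). That median was 0.048 relative to the other lineages, so these together had a difference of like size, and its source there was not tested. Ccn1, a matrix signal, was 4.16-fold higher, Egln1, an oxygen sensor, 3.77-fold, and Jun 4.80-fold (4.46 to 5.16). Jun belongs to the dissociation stress list, of which 5 of 8 members were at least 2-fold higher in endoderm (median 1.21), with Egr1 at 27.6 against 1.90 CPM, and 4 of 7 in embryonic cells (median 0.69). Lefty1, an inhibitor of NODAL signals made by anterior visceral endoderm, was 3.99-fold lower (3.57 to 4.47), although 1 cell held 7.02% of its day 4 UMIs, and Dkk1, a WNT inhibitor of the same cells, was at 72.2 against 164 CPM. Dppa5a (3.22-fold), the meiotic gene Sycp3 (2.56-fold) and Rpa3, of the replication protein A complex, (2.46-fold) were lower as well. The absorptive and secretory visceral endoderm list had a median of 0.11, with Rbp4, the retinol carrier, 3.29-fold higher and Ttr, the thyroxine carrier, at 1497 against 1929 CPM.

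Trophoblast cells had like levels of their stem cell genes in both libraries. The extraembryonic ectoderm list had none of its 12 members past 2-fold (median log2 ratio 0.19, percentile 50.8), with Elf5 at 183 against 228 CPM and Cdx2 at 82.2 against 72.5. Imprinted genes, read from 1 parental copy, had 5 of 9 members at least 2-fold higher at day 5 early (median 0.86, percentile 100), although Meg3 and Rian among them are abundant in the other lineages, with Meg3 at 225 CPM in the embryonic cells of that library, and relative to the other lineages the list median was -0.22. The largest trophoblast ratios rested on few cells: 1 of 362 cells held 1005 of the 1007 Acta2 UMIs and 747 of the 749 Tagln UMIs of day 5 early, both smooth muscle genes, and 3 cells, that one among them, held 1377 of the 1382 UMIs of Spp1, a secreted phosphoprotein. The first of these cells also held 57 of the 67 UMIs of the collagen gene Col1a1, and none of the 3 had an Elf5 UMI. Other trophoblast genes were not looked at in these cells, so their place in trophoblast is not certain. The ratio was at least 459-fold for Acta2, and it was 205-fold for Tagln and 210-fold for Spp1. Without those cells 2 Acta2 UMIs were left against 0 at day 4, which gives no fold, and the ratios were 0.549 (0.0523 to 3.36) for Tagln and 0.765 (0.201 to 2.54) for Spp1, so that neither was told apart from day 4. Hnrnpa0, an RNA-binding protein gene, was higher at 334 against 133 CPM (interval of the fold 2.38 to 2.63). Rpa3 (2.60-fold), Ost4 of the glycosylation complex (2.36-fold), Ndufb3 of respiratory complex I (2.29-fold) and Lsm7 of the splicing machinery (2.28-fold) were lower. The log2 ratios relative to the other lineages were -0.20 for Hnrnpa0, 0.042 for Ost4 and 0.048 for Lsm7, so these differences were shared by the lineages.

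Part of what set day 5 early apart from day 4 was seen in all 3 lineages alike. Across 2008 genes at 50 CPM or more in every lineage, the log2 ratios of embryonic cells correlated with those of endoderm at Pearson r = 0.872 and with those of trophoblast at r = 0.885, and endoderm and trophoblast correlated at r = 0.911 (across genes, which are not independent replicates). Genes in the bottom quartile of transcript length lay apart from those in the top quartile by -0.51 in embryonic cells, -0.55 in endoderm and -0.51 in trophoblast (bottom minus top quartile of the median log2 ratios), which is the side on which Rpa3, Ost4, Ndufb3 and Lsm7 lie. The random lists were matched on mean expression and not on length, so the percentiles of this comparison do not take out that trend. The median gene was shifted by 0.10, 0.12 and 0.11 log2 in the 3 lineages, where mitochondrial and ribosomal protein genes held 26.6% of embryonic UMIs at day 4 and 22.2% at day 5 early. Relative to the other lineages, the streak list of embryonic cells still had a median of 1.85, while the stress list had -0.11.

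The second comparison, day 5 mid against day 5 early, asks what more advanced gastrulation looked like at the same age. Streak and mesoderm genes of embryonic cells had like levels in both libraries. None of the 10 measured streak genes or the 7 nascent mesoderm genes differed by 2-fold (medians -0.0096 and -0.048). T stood at 143 CPM at day 5 early and 150 at day 5 mid, Mixl1 at 90.5 and 93.7, and Eomes at 186 and 173, while Mesp1 was 1.45-fold higher at day 5 mid, with 557 against 384 CPM. Bmp4, a signal of extraembryonic mesoderm, was at 12.2 against 5.71 CPM, and Hand1, a regulator of that tissue, at 34.5 against 28.4. The median gene was shifted by -0.18 log2 in embryonic cells, -0.16 in endoderm and -0.15 in trophoblast between these libraries, and relative to that shift (median-of-ratios scaling) the nascent mesoderm median was 0.051.

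Several list medians were below 0 in the embryonic cells of day 5 mid, with few members past 2-fold. The naive pluripotency list had 3 of 8 members at least 2-fold lower (median -0.39), with Zfp42 at 12.8 against 30.1 CPM, the formative and primed list a median of -0.42 with no member past 2-fold, and the epithelial list a median of -0.61 (percentile 0.05) with the junction gene Ocln past 2-fold and Cdh1 at 44.2 against 72.4 CPM. Of the NODAL pathway list (median -0.41), 1 of 5 measured members, Lefty1, was at least 2-fold lower (2.40-fold, 2.28 to 2.53). With median-of-ratios scaling these medians were smaller, at -0.27, -0.24, -0.43 and -0.23 in that order, relative to the other lineages they were -0.50, -0.12, -0.23 and -0.035, and the naive median was -0.15 without the naive-like cluster. Kcnq1ot1, a long noncoding RNA of an imprinted cluster, (2.31-fold), the stress-responsive Jund (2.25-fold) and Cyb5b of the mitochondrial membrane (2.14-fold) were also lower. The stress list had a median of -0.67 in embryonic cells, -0.84 in endoderm and -0.41 in trophoblast, the opposite side from the first comparison. Higher at day 5 mid were the histone genes Hist1h2ap (925 against 146 CPM, 6.35-fold, 6.21 to 6.49) and Hist1h2ae (2.98-fold), Uba52, which encodes ubiquitin fused to a ribosomal protein, (4.14-fold) and Uqcr11 of respiratory complex III (2.92-fold).

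Endoderm showed the matrix genes lower again at day 5 mid. The parietal endoderm list had 3 of 10 members at least 2-fold lower and none higher (median -0.67, percentile 0), with Lamc1, a laminin chain, 2.28-fold lower (2.18 to 2.39) and Col4a1 at 842 against 1556 CPM. That median was -0.44 relative to the other lineages, and cluster 1, with parietal endoderm markers, was 20.2% of endoderm at day 5 early and 15.3% at day 5 mid, so the mix of cells also differed. The anterior visceral endoderm list had a median of -0.55, Sfrp1, a WNT-binding protein gene, was 2.99-fold lower (2.74 to 3.28), and Eva1a, of autophagy, 2.44-fold lower. Rbp4 was 2.44-fold lower with 1 cell holding 10.1% of its day 5 early UMIs, and 2.20-fold lower without that cell, while Ttr was at 2404 against 1497 CPM. Fxyd2, a subunit of the sodium pump, was at 415 against 143 CPM, Fmc1, of mitochondrial ATP synthase assembly, 2.94-fold higher, Hist1h2ap 7.62-fold and Uba52 5.46-fold.

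In trophoblast, the extraembryonic ectoderm list had a median of -0.05, and 1 of its 12 members, the homeobox gene Rhox9, was past 2-fold (393 against 891 CPM). Elf5 was at 173 against 183 CPM and Eomes at 97.2 against 97.4. The epithelial list had a median of -0.53 and the imprinted list -0.58, and Cebpb, a transcription factor, was 2.29-fold lower (2.07 to 2.54). Acta2 (39.5-fold), Tagln (21.1-fold) and Spp1 (2.91-fold) were lower by the rule used, with the same few cells of day 5 early behind them. Without those cells the sign turned, with Acta2 12.7-fold (3.20 to 110), Tagln 17.7-fold (4.58 to 151) and Spp1 94.5-fold (40.2 to 292) higher at day 5 mid. No cell was removed at day 5 mid, and the spread of these counts over cells was not tested. There cluster 14 (196 cells), the cluster of the removed cells, held 519 of the 522 Spp1 UMIs and 27 of the 28 Acta2 UMIs. At day 6 the same cluster held 10 Spp1 UMIs in 1184 cells. With some other cell filters Acta2 was at or under the floor in both libraries. So removal from day 5 early alone gives no direction for these genes. Hist1h2ap (6.83-fold), Uba52 (4.74-fold), Hist1h2ae (3.92-fold) and the LIM gene Crip1 (2.97-fold) were higher.

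Most of the second comparison was shared by the lineages. Across 2083 genes the log2 ratios correlated between lineages at r = 0.95, 0.928 and 0.924 (embryonic with endoderm, embryonic with trophoblast, endoderm with trophoblast). Relative to the other lineages, the histone and ubiquitin genes of embryonic cells were no longer higher, with log2 ratios of -0.18 for Hist1h2ap, -0.29 for Uba52 and -0.15 for Hist1h2ae.

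The third comparison, day 6 against day 5 mid, asks what set the structures with extraembryonic membranes apart. In embryonic cells, extraembryonic mesoderm genes were higher at day 6, with all 6 measured members at least 2-fold above day 5 mid (median log2 ratio 1.77, percentile 100). Hand1 stood at 101 against 34.5 CPM, Foxf1, a mesoderm regulator of allantois and yolk sac, at 20.4 against 3.79, Bmp4 at 54.5 against 12.2 and Pmp22 at 83.9 against 19.8. Of 5 measured genes of endothelium and blood progenitors, 4 were at least 2-fold higher (median 0.86), with the receptor gene Kdr at 37.3 against 17.7 CPM, Etv2, which directs cells to that fate, at 58.3 against 24.6, and Lmo2 at 7.21 against 1.70. The globin genes Hba-x and Hbb-y were at 4.80 and 4.24 CPM at day 6 and had no UMI at day 5 mid, and Hba-x had been at 4.95 CPM at day 4.

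Streak and mesoderm genes were lower over all embryonic cells of day 6, although cluster 23, named for streak markers, held 2076 of these 9194 cells. The streak list had 4 of 10 members at least 2-fold lower (median -0.86, percentile 0), with Sp5 at 57.7 against 144 CPM and Nodal at 23.6 against 54.5, and T was at 77.7 against 150. Nascent mesoderm genes had 4 of 7 (median -0.74), with Mesp1 3.07-fold lower at 181 against 557 CPM and Mesp2 8.82-fold. The formative and primed list had a median of -0.03, although Pou5f1 was at 532 against 888 CPM. Slpi, a protease inhibitor gene, was 10.4-fold lower (9.80 to 11.1), Nefl, a neurofilament gene, 4.58-fold and Psors1c2 3.97-fold. The p53 target list had 3 of 8 members at least 2-fold lower (median -0.95, percentile 0), with the cell cycle inhibitor Cdkn1a at 48.6 against 148 CPM and Phlda3 at 46.9 against 170, and its medians were -0.24 in endoderm and -0.40 in trophoblast.

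**Figure D3:**
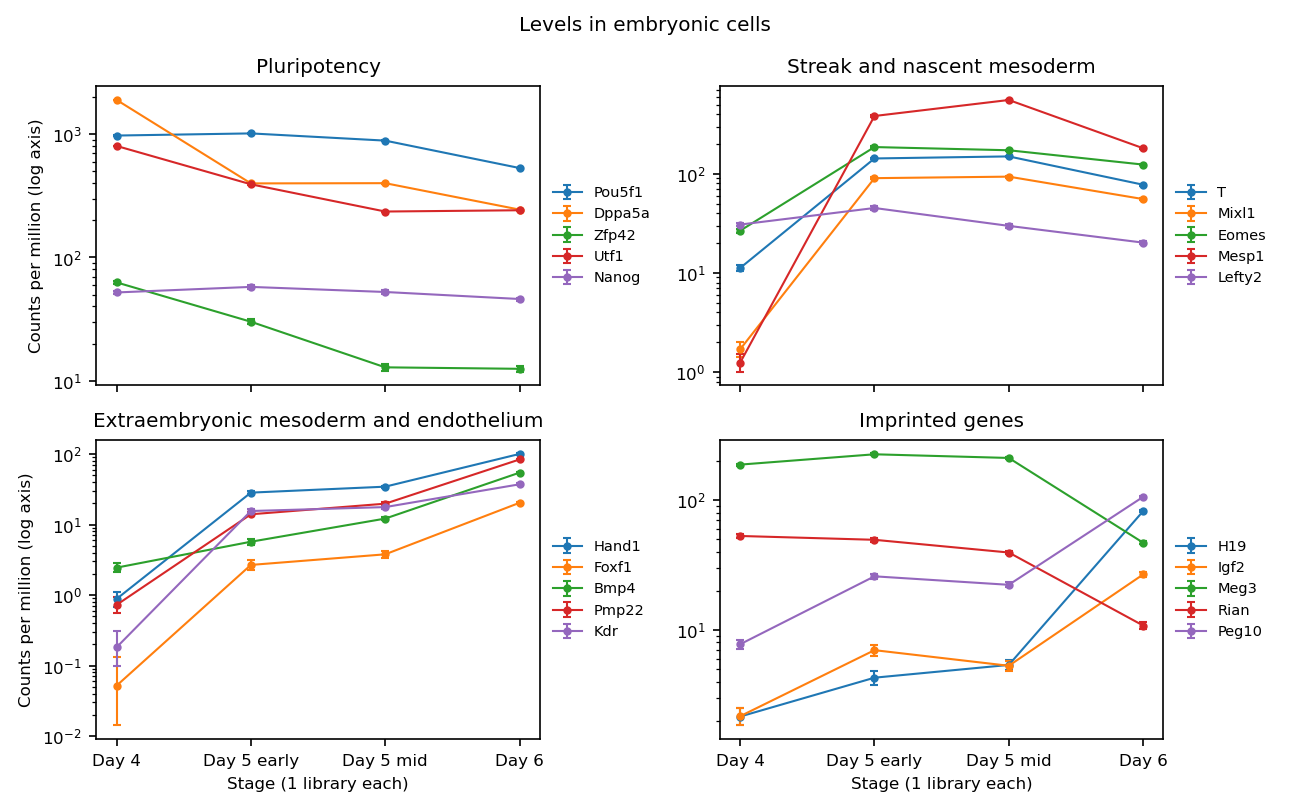
Levels of 20 genes in embryonic cells (CPM, log axis) at the 4 stages (x axis, 1 library each), by gene group. Points are library sums and whiskers exact 95% Poisson intervals for counting error only. Mesp1 was at 1.24 at day 4 and 384 at day 5 early, and H19 at 5.37 at day 5 mid and 82.0 at day 6.

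Imprinted genes parted in 2 directions in the embryonic cells of day 6. The growth-linked noncoding RNA H19 was 15.3-fold higher (13.9 to 16.8), with cluster 19 holding 6413 of its 8693 UMIs and cluster 20 at 18.5 CPM, and Peg10 and Mest were also at least 2-fold higher. H19 at day 6 was also at 17.9 CPM in naive-like cluster 4 and 18.7 in trophoblast, against 330 in endoderm. So free RNA was not excluded for the level of cluster 20. The growth factor gene Igf2 was at 26.7 against 5.29 CPM, a level so far below the 390 CPM of trophoblast that free RNA was not excluded. In the other direction, the maternally read noncoding RNAs Meg3 and Rian were lower, Meg3 with 46.9 against 211 CPM (4.49-fold, 4.35 to 4.64) and Rian with 10.8 against 39.4. Genes of glycolysis and hypoxia were higher, 7 of 12 by at least 2-fold (median 1.13, percentile 100), with the glucose transporter gene Slc2a1 at 179 against 76.4 CPM and the mitophagy gene Bnip3 at 135 against 40.7. Ndufa4l2, a mitochondrial gene induced by low oxygen, was 7.41-fold higher (6.96 to 7.89), the sugar-phosphate enzyme gene Pgm1 5.74-fold and Anxa2, a membrane-binding gene, 12.8-fold. Ndufa4l2 and Pgm1 were among the leading genes of streak-like cluster 23, and how far that cluster carried their ratios was not tested. Embryonic cells of day 6 also had 7 of 9 visceral endoderm genes at least 2-fold higher (median 0.98), at levels far below the endoderm of that library: Apoa1 was at 9.98 CPM against 860 there, and Ttr at 25.4 against 2168.

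Endoderm at day 6 had higher levels of some lipoprotein and carrier genes. The absorptive and secretory visceral endoderm list had 3 of 12 members at least 2-fold higher (median 0.55, percentile 100), with Apoa1 at 860 against 226 CPM, Rbp4 4.69-fold higher (4.54 to 4.85) at 707 against 151, and Trf, the transferrin gene, at 27.8 against 8.78, and Apoa2, of the same lipoprotein family, was 5.25-fold higher. The carrier gene Ttr, at 2168 CPM, was below its day 5 mid level given above. The endocytic receptor genes Amn and Cubn had like levels, with 819 against 808 and 498 against 500 CPM. Pdpn, a surface glycoprotein gene, was 13.7-fold higher (11.3 to 16.9) and Cdkn1c, an imprinted cell cycle inhibitor, 6.55-fold. The anterior visceral endoderm list had a median of 0.44, with the WNT inhibitor gene Sfrp5 at 27.3 against 12.8 CPM, and the BMP target list a median of -0.39. Mpc1, of the mitochondrial pyruvate carrier, (2.86-fold), the polarity gene Crb3 (2.62-fold), Rpp25 of ribonuclease P (2.51-fold) and Dppa5a (2.48-fold) were lower. Relative to the other lineages the absorptive list had a median of -0.74, since its members were also higher in embryonic cells and trophoblast, at low levels.

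Trophoblast cells of day 6 had lower levels of several stem cell genes. Elf5 was at 107 against 173 CPM, Cdx2 at 46.2 against 71.7 and Eomes at 67.0 against 97.2, none by 2-fold, while the homeobox genes Rhox6 (1502 against 668 CPM) and Rhox9 (924 against 393) were more than 2-fold higher, and the extraembryonic ectoderm list of 12 had a median of -0.21. Without doublet removal that median was -0.30. Nr0b1, a nuclear receptor gene of stem cells, was 2.21-fold lower and the signal gene Wnt6 2.26-fold, as were Rbm38, an RNA-binding p53 target, (2.53-fold) and Nat8l (2.14-fold). Glycolysis and hypoxia genes were higher, 5 of 12 by at least 2-fold (median 0.89), with Pgk1 at 966 against 453 CPM, Bnip3 4.03-fold higher (3.64 to 4.47) and Pgm1 4.18-fold. Nrk, a kinase gene of the placenta, was 5.08-fold higher (4.62 to 5.60) and Myl4, a myosin light chain gene, 4.03-fold. Cluster 13, led by Rhox9 and Rhox6 with Myl4 among its leading genes, was 8.91% of trophoblast at day 5 mid and 18.4% at day 6, and how far this mix carried the differences in these genes and the stem cell genes was not tested. The giant cell gene Prl3d1 had no UMI in any trophoblast library.

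The third comparison was less alike between lineages than the others, with r = 0.498 between embryonic cells and endoderm, 0.725 between embryonic cells and trophoblast, and 0.584 between endoderm and trophoblast across 2021 genes. The day 6 library was also the shallowest per cell and its barcodes exceeded the cells loaded, and genes of the bottom quartile of length lay apart from the top quartile by -0.33 in embryonic cells, -0.19 in endoderm and -0.17 in trophoblast.

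**Figure D4:**
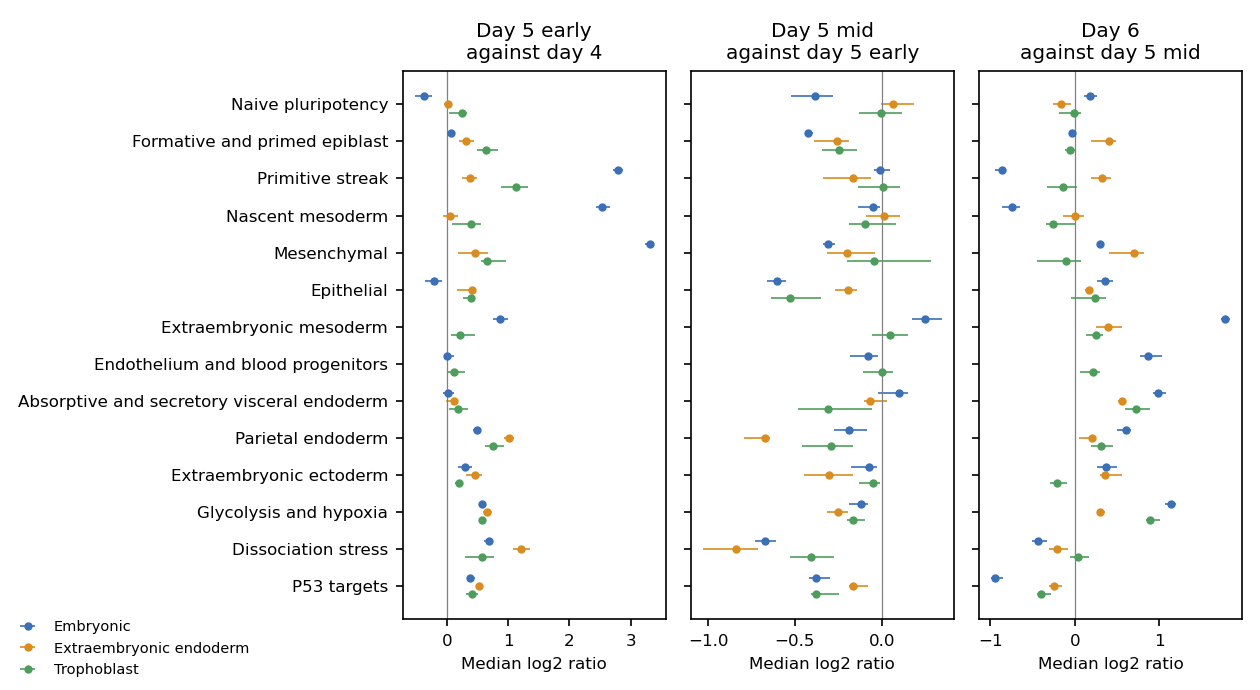
Median log2 ratio (x axis) of 14 gene lists (y axis) in each consecutive comparison (panels, each with its own scale), by lineage, for lists with at least 3 measured members. Whiskers are the central 95% of medians over redrawn Poisson counts. In embryonic cells the streak list stood at 2.79, -0.0096 and -0.86 in the 3 comparisons.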

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

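All results of this part were picked out after the values were seen. In 2 genes at 50 CPM or more in both lineages, embryonic cells and endoderm differed by at least 2-fold in opposite directions in the same comparison. With 1 library per stage the differences between lineages were not tested. Meg3 was also lower in embryonic cells and higher in endoderm at day 6, but by less than 2-fold in endoderm (435 against 240 CPM). S100a10, a partner of the membrane-binding annexins, was 2.51-fold higher at day 5 early than at day 4 in embryonic cells (388 against 155 CPM) and 2.03-fold lower in endoderm (279 against 568 CPM), a gap of 2.34 between the log2 ratios. Mt2, a metallothionein gene, was 2.83-fold higher at day 6 than at day 5 mid in embryonic cells (187 against 65.9 CPM) and 2.06-fold lower in endoderm (296 against 610 CPM), a gap of 2.53.

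A cluster that took no lineage name held 187 cells at day 6 and expressed genes active in endoderm, definitive or visceral, and in its precursors. In these cells Sox17 stood at 222 CPM (95% interval 202 to 244, counting error only), Foxa2 at 78.5 CPM (66.8 to 91.6) and Trh, a hormone precursor gene, at 330 CPM (306 to 356), where 0 counts would have allowed 1.81 CPM. The embryonic lineage of that library had 4.51, 5.87 and 137 CPM, and the extraembryonic endoderm had 154, 45.7 and 12.3 CPM, so Sox17 and Foxa2 do not part definitive from visceral endoderm. Trh was also at 468 CPM in naive-like cluster 4 and 233 CPM in epiblast-like cluster 20 of that library, so it does not mark endoderm here. The cluster was singled out by its raised markers of a list that holds Sox17, Foxa2, Trh, Gsc and Lhx1, so these levels are no separate support. Cer1 (53.5 CPM), Gsc (80.5), Lhx1 (219) and Cfc1 (261), active in anterior endoderm or streak, were also above their embryonic levels of 0.123, 28.7, 80.3 and 35.0 CPM. Other genes of such tissue were not high, with Chrd at 2.94 CPM (6 counts), T at 47.6 CPM against 77.7 CPM in embryonic cells, and Pyy at 0 counts. The cluster had the green reporter (EGFP 984 CPM, against 574 CPM in embryonic cells, 201 CPM in trophoblast and 53.5 CPM in extraembryonic endoderm) and little Xist (3.92 CPM). The Y-linked gene Ddx3y was at 48.6 CPM, against 39.9 CPM in embryonic cells and 4.42 CPM in extraembryonic endoderm. DSRED was at 9.32 CPM, against 9.65 and 50.6 CPM in that order. EGFP, Ddx3y and DSRED thus lay near or above the embryonic levels and apart from those of extraembryonic endoderm. The cluster had lower levels than extraembryonic endoderm of the visceral genes Ttr (66.2 against 2168 CPM), Dab2 (61.8 against 1581) and Apoa1 (92.7 against 860), each above its embryonic level (25.4, 21.9 and 9.98 CPM). It was left unnamed because its leading genes held more markers of another lineage, and its cells enter no lineage comparison and are counted only in sums over all cells.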

How the results depend on the processing

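No paired analysis was possible because each stage is 1 library. Of the alternatives, those chosen after seeing the data were the shares among named cells, the naive-like cluster set aside, the ratios relative to the other 2 lineages and the removal of the cell with the most counts or, for Spp1, of the 3 cells with the most. Depth limits genes under a few CPM, most of all in trophoblast at day 5 early (362 cells), and no setting gives a spread between structures or libraries.

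Embryonic shares (in the order day 4, day 5 early, day 5 mid, day 6) stayed above those of the other lineages. They were 46.2%, 42.6%, 57.8% and 64.0% with a UMI minimum of 1000, and 53.8%, 56.4%, 64.4% and 66.9% with a higher one. Naming each cell by its own markers gave 55.5%, 57.4%, 65.5% and 64.1%, the share of named cells 59.1%, 60.7%, 69.0% and 69.1%, and setting the naive-like cluster aside 43.9%, 46.3%, 59.3% and 63.7%. Without doublet removal day 4, day 5 mid and day 6 were at 47.7%, 58.4% and 62.9%, and with the automatic threshold day 5 early and day 5 mid were at 50.4% and 62.1%. A mitochondrial maximum of 5% gave 51.4% at day 5 early and 68.3% at day 6, one of 20% gave 63.6% at day 6, and resolution 2 gave 67.4% at day 6. With a lower resolution or more variable genes all 4 stayed within their intervals. Day 6 was not above day 5 mid with each cell named by its own markers, and the intervals overlapped among named cells (68.3 to 69.9 against 67.9 to 70.1). Finer shares moved more: the germ cell-like share ranged from 0 to 6.21% at day 4 and the extraembryonic mesoderm-like share from 7.85% to 19.9% at day 6.

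The list medians treated as main results moved as follows, and the cause was not tested. The streak median at day 5 early against day 4 (2.79) was 2.70 with median-of-ratios scaling, 2.71 without the naive-like cluster, 3.23 and 2.36 with pseudocounts 0.1 and 5, 3.19 over members at 5 CPM or more, 2.27 over all cells and 1.85 relative to the other lineages. The nascent mesoderm median there (2.53) was 3.53 and 1.69 with those pseudocounts, 3.34 over members at 5 CPM or more and 1.42 over all cells. At day 5 mid against day 5 early (-0.048) it was 0.030 without mitochondrial and ribosomal genes, 0.051 with median-of-ratios scaling, -0.16 as a mean over cells, -0.15 over members at 5 CPM or more, 0.061 over all cells and -0.15 relative to the other lineages, so no direction is given for it. The extraembryonic mesoderm median at day 6 (1.77) was 1.69 as a mean over cells, 1.93 and 1.14 with pseudocounts 0.1 and 5, 2.05 over members at 5 CPM or more, 1.23 relative to the other lineages and 0.94 over all cells. The absorptive visceral endoderm median of endoderm at day 6 (0.55) was 0.59 without mitochondrial and ribosomal genes, 0.49 as a mean over cells, 0.60 over all cells, and reversed to -0.74 relative to the other lineages. The extraembryonic ectoderm median of trophoblast at day 6 (-0.21) was -0.30 without doublet removal, 0.040 over all cells and -0.81 relative to the other lineages.

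Reversals among the other lists and genes came from the settings below. Relative to the other lineages, in embryonic cells the stress list became -0.11 at day 5 early and 0.16 at day 5 mid, Hist1h2ap -0.18, Uba52 -0.29 and Hist1h2ae -0.15 at day 5 mid, and the Y-linked list -0.40 at day 6. In endoderm at day 5 early the WNT target list became -0.30 and Rpa3 0.066. In trophoblast at day 5 early the streak list became -0.33, the glycolysis list -0.0051, the imprinted list -0.22, Hnrnpa0 -0.20, Ost4 0.042 and Lsm7 0.048, and at day 5 mid Hist1h2ap -0.025 and Uba52 -0.0077. This setting takes out what the lineages share, which is why those signs turned. Over all cells the NODAL list of the endoderm comparison at day 5 early was 0.14 and the feeder fibroblast list of trophoblast at day 6 was 0.19. In trophoblast without the cell with the most counts, Acta2 was at 3.67 at day 5 mid, and Tagln at -0.86 at day 5 early and 4.15 at day 5 mid. Without the 3 cells with the most counts, Spp1 was at -0.39 at day 5 early and 6.56 at day 5 mid. These cells were removed from day 5 early alone, so no direction is given for Acta2, Tagln and Spp1 at day 5 mid. With a UMI minimum of 1000 Tagln was at -0.84 and 3.57, with a mitochondrial maximum of 5% at -0.064 and 2.75, and with one of 20% at 2.61 at day 5 mid. In these settings Acta2 was at or under the floor at day 5 early. So the cell with 1005 Acta2 and 747 Tagln UMIs was not in the trophoblast sum, and why it was not was left untested. Spp1 kept its sign but moved at day 5 mid with that UMI minimum and both mitochondrial maxima, so its level there also depended on the settings. No value is given for Acta2 at day 5 early against day 4 without the cell with the most counts, or in either comparison with the UMI minimum of 1000 or either mitochondrial maximum, since both libraries were then at or under the floor.

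Of the 72 named genes, 64 were also named with a UMI minimum of 1000, 66 with the higher one, 62 and 65 with mitochondrial maxima of 5% and 20%, 70 without doublet removal, 67 with the automatic threshold, and 7 without the filter on low levels, which lets genes with few counts lead.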

Other observations

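Of the tests in this part, those chosen only after the result was seen were the length trend of the day 5 early library, all for DSRED, and for Meg3, Rian and EGFP those on the Meg3-rich class, development, the library-wide loss and the mixture. The cluster with markers of the naive state, the pluripotency of the blastocyst, held cells with the reporter of the embryonic lineage and cells with that of endoderm. By a 5-fold excess of one reporter, 60.4% of its cells at day 4 were mostly EGFP and 28.8% mostly DSRED, with 74.6% and 14.3% at day 5 early and 49.2% and 33.9% at day 5 mid. Its Y-linked level at day 4 was 121 CPM in the EGFP cells and 3.53 CPM in the DSRED cells. At day 6, 25.8% were mostly EGFP, 0.613% mostly DSRED and 73.6% had neither excess, and Y-linked genes stood at 122 CPM in the EGFP cells and at 26.6 CPM in those with neither. So part of this cluster had the reporter and the low Y-linked level of the endoderm lineage, and the embryonic lineage was also recomputed without the cluster.

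Genes abundant in fibroblasts, on which trophoblast stem cells are often grown, were at low levels in trophoblast. Col1a1 was at 0 counts at day 4, at 5.08 CPM at day 5 early (57 of its 67 UMIs in 1 cell, which also held 1005 Acta2 and 747 Tagln UMIs and no UMI of the trophoblast gene Elf5), 7.81 CPM at day 5 mid and 0.401 CPM at day 6, and the 3 measured genes of the feeder fibroblast list (Col1a1, Col1a2 and Thy1) were all at least 2-fold lower at day 6 than at day 5 mid (median log2 ratio -1.52). Over all cells of the library that median was 0.19, and the source of the counts of day 5 mid and day 6 was not tested.

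Short transcripts were lower at day 5 early than at day 4 in all 3 lineages (-0.51, -0.55 and -0.51, log2, bottom minus top quartile of transcript length). Against a trend of that library alone, the next step, day 5 mid against day 5 early, gave back at most 0.15 log2 (0.15, 0.13 and 0.00 in the 3 lineages), and day 5 mid against day 4 was still at -0.33, -0.35 and -0.54, as a difference that continues to day 5 mid needs. The bound set in advance for a library trend, on day 5 early against day 4, was met, yet it could not part day 5 early from day 4 as the library that stands apart, which is why the later test was used. A difference of the day 4 library alone gives the same values, so stage and library cannot be told apart. In cells with few signs of stress the difference was -0.33 in embryonic cells, -0.28 in endoderm (50.8% kept, the smallest share) and -0.46 in trophoblast, which met the bound set in advance against stressed cells in trophoblast (37 such cells at day 5 early) and not in the other lineages (13 each), where a share of stressed cells stays open.

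DSRED, whose line the labels do not state, was in endoderm at 1679 CPM at day 4 and 50.6 CPM at day 6. The tables argue against endoderm made by the other lines: EGFP and Y-linked genes of the day 6 endoderm were at most 9.78% of their embryonic level, and Xist was 1.31% of its trophoblast level. They also argue against fewer cells of parietal cluster 1, as visceral endoderm-like cells (cluster 0 at day 4, mostly cluster 21 at day 6) had 3.77% of their day 4 level. Silencing of the reporter over the days was not tested and stays open, as does a difference of the library.

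Meg3 and Rian, neighbours in 1 imprinted cluster, and EGFP were lower in embryonic cells at day 6 than at day 5 mid. A library-wide loss is argued against by endoderm, where Meg3 at day 6 was 181% of its day 5 mid level. A different mix of the embryonic clusters with at least 50 cells at day 5 mid is argued against. The lowest of them still had at least 1.47 times the day 6 level: Meg3 104 against 46.9 CPM, Rian 21.4 against 10.8 and EGFP 846 against 574. Clusters 20 and 23, 40.4% and 22.6% of the embryonic cells of day 6, held 22 and 5 cells at day 5 mid, so a mix with them was not covered. For EGFP such a mix stays open, as the 22 cells of cluster 20 at day 5 mid were at 584 CPM (466 to 723). Their Meg3 was at 146 CPM (90.3 to 223). The bound set in advance, on Meg3 within classes, decided nothing. The epiblast-like cells (19.1% of day 5 mid) were mostly cluster 7, which failed the class check, at day 5 mid and cluster 20 at day 6. The naive-like cluster (80.8%) holds cells with either reporter. Germ cell-like cluster 17 and cluster 19 passed the class check and held cells of both libraries. Within them Meg3 at day 6 was at 11.3 against 183 and at 24.1 against 206 CPM, and Rian in cluster 19 at 6.06 against 56.1. These clusters were picked after the values were seen. A mixture of cells at day 5 mid EGFP levels with cells lacking EGFP would leave 59.8% of embryonic cells without an EGFP count. Of the day 6 cells 41.1% (40.1 to 42.1) had none, nearer to, but above, the 38.3% of the same lower level in all cells. So that mixture is argued against, while a mixture of other levels stays open. The variance ratio of 0.921 in epiblast-like cells (clusters 7 and 20) decides nothing, since that ratio falls with the mean (2.13 and 1.07 counts), so its bound was badly chosen. Development from day 5 mid to day 6 was taken to leave Meg3 near its day 5 mid level in naive-like cells, as cells that had not developed further. Mostly EGFP naive-like cells had 43.8% (32.8 to 57.8) of that level, on the side against development, yet the interval reached past the bound set against it. A difference between the libraries that spares endoderm would give the same value, so development stays open.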
